A study of Mus musculus with 2 samples.

How the data were processed

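Gene expression was measured in 2 cultures of mouse CD4 T cells with 1 Affymetrix expression array each. Per the labels' protocols, CD4 T cells were taken from spleens of C57BL/6 mice by magnetic sorting at a purity above 98%. They were stimulated with plate-bound antibody against the T cell receptor and with antibody against CD28 for 2 days in CD103+ Th1 or Th1 medium, and harvested 3 days later. Total RNA was extracted with Trizol and labelled with biotin by in vitro transcription, per the labels' protocols. The labels do not say how many mice gave cells, and they put 1 array in each group, so neither the spread between cultures nor that between arrays could be estimated.

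The deposited table holds 1 signal intensity per probe set and array on a linear scale in arbitrary units, and the submitters' processing notes name the Affymetrix GCOS software, with no version given. A probe set is a group of short probes against 1 transcript, which that software condenses to 1 signal. The scaling target and any filter were not given in the sources used here. The values were positive on both arrays, the medians were 78.0 and 78.8, and the 2% trimmed means were 498 on both, so no further scaling was applied. Such signals have no detection call in the table used here, and low values are dominated by background. A floor was therefore set at the median signal over both arrays, 78.5. A value under the floor was set to the floor, a probe set under it on both arrays received no ratio, and one under it on 1 array gave a bound, written "at least N-fold". About 49.9% of probe sets in CD103+ Th1 and 50.1% in Th1 lay above the floor.

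Probe sets were named through the platform annotation supplied with the values, updated by gene identifier to the symbols of the mouse GRCm38.p6 gene table. Of 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none listed. Of those with 1 symbol, 34741 matched the gene table. Only probe sets with 1 symbol were named, which gave 18194 genes. For each gene the probe set with the highest mean log2 signal was used. Of 11194 measured genes, 10045 lay above the floor on both arrays, 467 in CD103+ Th1 alone and 682 in Th1 alone. Levels of different probe sets were not set against each other. Genomic coordinates were not used, except the order of genes in the gene table.

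The ratio of both signals was taken per gene, CD103+ Th1 over Th1, and genes with at least 2-fold difference were counted. With 1 array per group no test was made. Gene lists were described by the median log2 ratio of their measured genes, with bounds at their bound, and by the percentile of this median among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called apart where its median lay outside the middle 95% of random lists, which 5% of lists do by chance. The 28 lists, the rules, the named genes and the alternatives were fixed before the data were examined. There were 9 primary lists on T helper programs, on responses to the cytokines in the media, on cytotoxic genes and on tissue residence. The rest covered homing, interferons, integrins, chemokine receptors, cytokines, inhibitory receptors, proliferation, metabolism, controls and other cell types. Of 595 list entries, 68 had no named probe set here and were not analysed.

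Named genes were the 12 with the highest and the 12 with the lowest ratio among genes at 4 times the floor or more on the brighter array with all measured probe sets in one direction. To these came 20 genes of T helper biology fixed in advance, and up to 4 members of each list with the largest absolute ratio, fewer for controls. Of the fixed genes, 1 is not reported here. A few further genes were chosen after their values were seen. These include Il18rap, the other IL-18 receptor chain gene. Il5, Il13, Ms4a1 and Pax5 were each named as under the floor, and Trgv4 beside Trgv1. Cdkn1a, Cdkn2b, Smad3, Prdm1 and Crtam were named as exceptions, and Cd74, Cd68 and H2-Ab1 beside other myeloid and dendritic cell markers. The closing sections say which of their genes were so chosen. Control probe sets for RNA quality were planned as a check and were not analysed here.

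The alternatives were medians set equal, quantile normalization, trimmed means set equal, a floor at the 25th or the 75th percentile, and a pseudocount equal to the 25th percentile with no floor. The others were the mean of all measured probe sets of a gene, only probe sets without suffix letters for shared transcripts, thresholds of 1.5-fold and 4-fold, and random lists without matching.

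The steps were tested on simulated data for the comparison of CD103+ Th1 with Th1, with 18194 genes and a noise SD of 0.2 per array on the log2 scale. All 50 genes planted at a log2 ratio of 2 and all 50 at -2 were called, against 26 of 50 at 1 and 20 of 50 at -1. Of 10622 unchanged genes, 2 were called. The simulated noise was the same at all signal levels and held no difference between cultures. Planted genes were drawn from bright genes only. These rates for genes therefore do not carry over to the calls in the data. Of 200 random lists of 20 genes among 11194 measured genes, 3.5% were called apart, and 18 of 20 lists shifted by 0.5 were. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.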

Results

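Splenic CD4 T cells of C57BL/6 mice were cultured for 5 days under 2 conditions, and total RNA of each culture was hybridised to an Affymetrix mouse expression array. The CD103+ Th1 condition contained IL-4 at 3 ng/ml, IFN-γ at 10 ng/ml and TGF-β at 3 ng/ml. The Th1 condition contained IL-12 at 1 ng/ml and an antibody against IL-4 at 1 µg/ml. CD103 is the integrin αE chain, encoded by Itgae, which pairs with integrin β7 and binds E-cadherin. Each condition had 1 array, so no difference below has a replicate check and no test or p-value is given. Every fold is the signal of the CD103+ Th1 array against that of the Th1 array, and "higher" or "lower" compares these 2 arrays. The number of arrays limits the precision. The 2 arrays gave 45037 probe sets each, with median signals of 78.0 in CD103+ Th1 and 78.8 in Th1 and trimmed means of 498 on both.

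The comparison asked how cells of the IL-4, IFN-γ and TGF-β culture differ from Th1 cells made with IL-12. The integrin gene Itgae was the most increased of the named genes, with a signal of 13248 in CD103+ Th1 and 82.1, close to the floor, in Th1, 161-fold higher, and its 2 probe sets had log2 ratios of 6.06 and 7.33. Cdh1, which encodes its ligand E-cadherin, was 74.6-fold higher on its 1 probe set (7023 against 94.1, also close to the floor). Foxp3, the transcription factor of regulatory T cells, was at least 20.6-fold higher. Ifng was 10.8-fold lower in CD103+ Th1, with signals of 529 and 5711. Of 11194 genes above the floor on at least 1 array, 564 were at least 2-fold higher in CD103+ Th1 and 545 at least 2-fold lower, together 9.91%. At 4-fold the counts were 108 and 86. In 96 of the higher and 93 of the lower genes the dimmer array lay under the floor, so that their folds are lower bounds. The 2-fold counts depend on the floor. They were 974 higher and 1206 lower with it at the 25th percentile, and 267 and 199 at the 75th.

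The other genes with the highest ratios were Cpd (at least 35.1-fold), Ldlrad4 (at least 33.9-fold), Rtp4 (at least 26.9-fold), Spsb1 (22.3-fold), Cd24a (17.9-fold), Pmepa1 (17.2-fold), Nt5e (16.7-fold), Car2 (at least 16.5-fold) and Trgv1 (16.5-fold). The Th1 signal of Spsb1, 97.0, was close to the floor. Nt5e encodes CD73, the ectoenzyme that makes adenosine, and Pmepa1 and Ldlrad4 encode inhibitors of TGF-β signalling. The genes with the lowest ratios, besides Ifng, were Ms4a4c (19.0-fold lower), Serpinf1 (18.5-fold), Ermn (at least 17.8-fold), Trat1 (12.6-fold), Ltb4r1 (10.1-fold), Eps8 (9.91-fold), H2-Q10 (9.86-fold), Cpm (at least 9.45-fold), Ffar2 (9.40-fold), Etv5 (at least 9.16-fold) and Cobll1 (8.66-fold). Ltb4r1 encodes the high-affinity leukotriene B4 receptor and Ffar2 a receptor for short-chain fatty acids. Several of these folds depend on the probe set taken. Log2 ratios of probe sets ranged from 0.29 to 5.08 for Ldlrad4, 1.09 to 5.13 for Cpd, 1.30 to 4.48 for Spsb1, 0.99 to 4.10 for Pmepa1 and 2.43 to 4.06 for Nt5e, and among the lower genes from -3.19 to -0.10 for Etv5, -3.24 to -0.97 for Cpm, -3.11 to -1.26 for Cobll1 and -4.16 to -2.62 for Ermn.

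**Figure D1:**
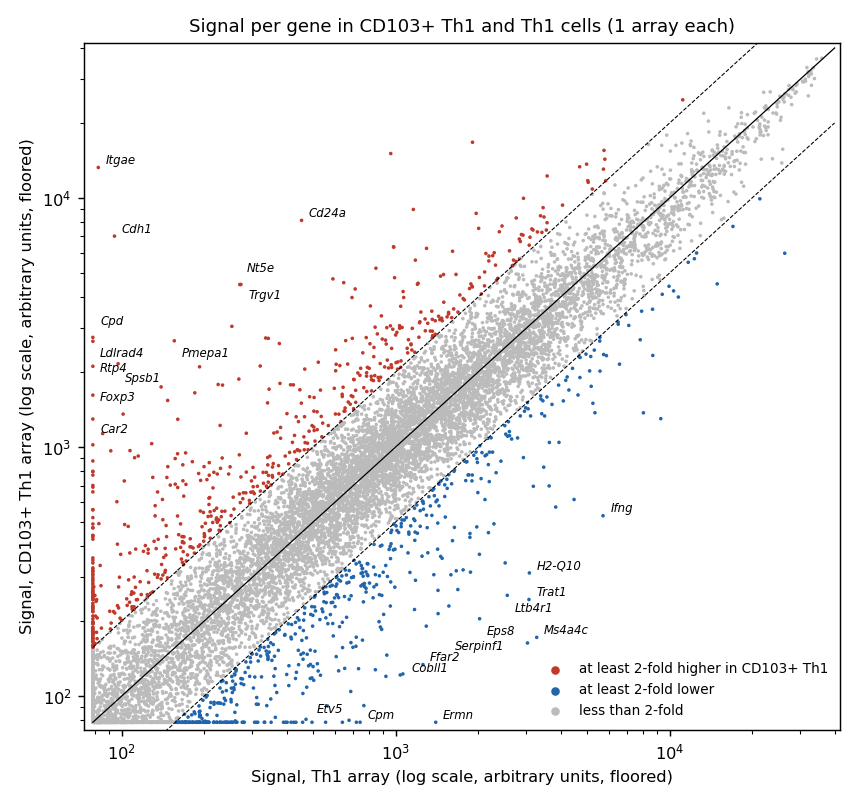
Signal of each gene above the floor on at least 1 array, in Th1 (x axis) and CD103+ Th1 (y axis) cells, both log scales in arbitrary units with values under the floor drawn at the floor. Red points mark the 564 genes at least 2-fold higher in CD103+ Th1 and blue points the 545 at least 2-fold lower; the solid line marks equal signals, the dashed lines 2-fold, and the labels the genes with the highest and lowest ratios, with Itgae at 13248 against 82.1.

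Genes of the Th1 program did not move together. Ifng, Tbx21, which encodes the Th1 transcription factor T-bet, and both IL-18 receptor chains were lower in CD103+ Th1, while Eomes, a T-box factor related to T-bet, was higher. Tbx21 had signals of 705 in CD103+ Th1 and 1510 in Th1, 2.14-fold lower, and Eomes had 3673 and 1043, 3.52-fold higher. Il18r1 was 3.30-fold lower and the chemokine gene Ccl5 3.70-fold lower, whereas the chemokine gene Xcl1 was at least 3.42-fold higher. Stat4, which transmits the IL-12 signal, was 1.74-fold higher, Il12rb2 1.49-fold lower and Runx3 1.33-fold higher, with Runx3 probe sets in both directions. Of 21 measured Th1 genes, 6 were at least 2-fold lower and 2 at least 2-fold higher. The median log2 ratio of the list was -0.05, at the 42.5th percentile of 10000 random lists matched on expression.

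Genes linked to Th2 cells were higher in CD103+ Th1, but the cytokine genes Il4, Il5 and Il13 were near or under the floor. Gata3, the Th2 transcription factor, was 3.39-fold higher (1361 against 401). The IL-4 receptor gene Il4ra was 2.38-fold higher, Il10 3.14-fold, the phosphatase gene Dusp4 3.28-fold and the chemokine receptor gene Ccr8 at least 3.48-fold. The Il4 signal was 88.7 in CD103+ Th1, just above the floor of 78.5, and 21.4 in Th1. Il5 and Il13 lay under the floor on both arrays, and Stat6 was 1.04-fold lower. Of 16 measured Th2 genes, 9 were at least 2-fold higher and 0 at least 2-fold lower, and the median log2 ratio of 1.18 lay above all the matched random lists (percentile 100). With a pseudocount in place of the floor the median was 0.78.

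Regulatory T cell genes were also higher in CD103+ Th1. Besides Foxp3 and Nt5e, the orphan receptor gene Gpr83 was at least 5.56-fold higher and Izumo1r, which encodes folate receptor 4, 2.92-fold higher. Of 18 measured genes of this list, 7 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.67 (percentile 100). Il9 was at least 6.25-fold higher (491 against 36.9), and Irf8 3.29-fold higher, with probe sets at 0.72 and 1.72 on the log2 scale, but 2 other genes of the Th9 list, Etv5 and Batf3, were lower, Batf3 7.27-fold. In the Th17 list, Ahr, which encodes the aryl hydrocarbon receptor, was at least 10.2-fold higher and the IL-6 receptor gene Il6ra 5.66-fold higher on its brightest probe set, while the cytokine genes Csf2 (at least 3.09-fold) and Il21 (at least 2.09-fold) were lower. The other Il6ra probe set had a log2 ratio of 0.92, under 2-fold. With the floor at the 75th percentile, 472, Il9, Ahr and Il6ra were no longer 2-fold higher, with log2 ratios of 0.06, 0.75 and 0.82. Only 8 genes of each of these lists were measured, with medians of 0.46 (percentile 98.5) for Th9 and 0.51 (percentile 99.6) for Th17. Both medians turned below 0 with a pseudocount in place of the floor, at -0.021 for Th9 and -0.11 for Th17, and the Th9 median was -0.10 with a higher floor.

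**Figure D2:**
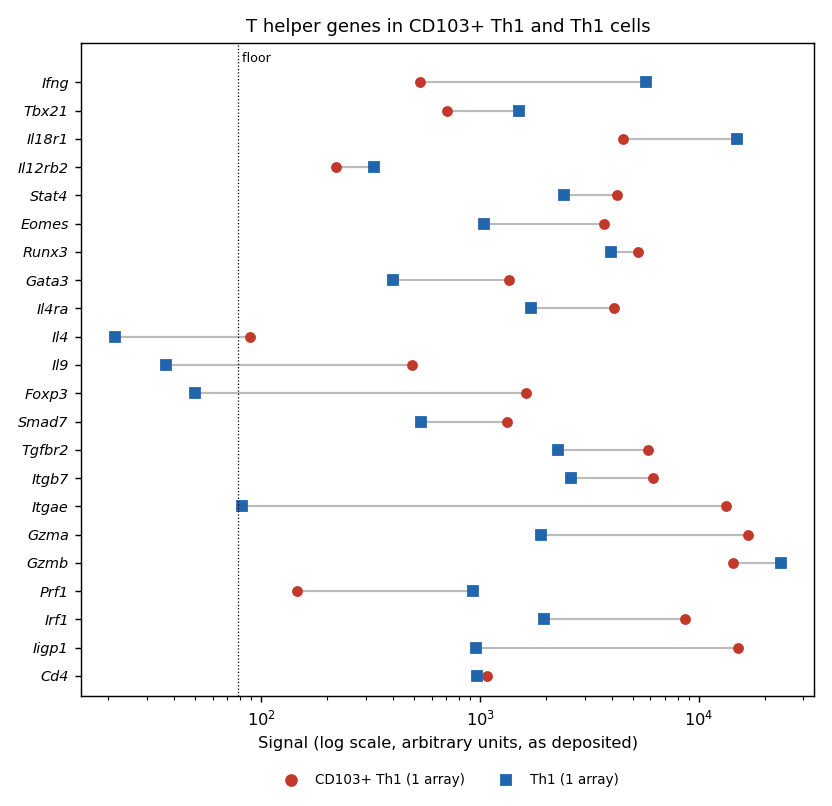
Signals as deposited (x axis, log scale, arbitrary units) of 22 T helper genes (y axis) in CD103+ Th1 (red circles) and Th1 cells (blue squares), 1 array each; the dotted line marks the floor of 78.5. Itgae, Foxp3, Il9 and Gata3 lay higher in CD103+ Th1 and Ifng, Il18r1 and Prf1 lower, while Cd4 was 1.11-fold higher.

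Genes that respond to TGF-β were higher in CD103+ Th1 as a group, with exceptions. Skil, which encodes a repressor of SMAD proteins, was 6.45-fold higher, and Smad7, an inhibitor of the pathway, 2.48-fold, both on the brightest probe set. Their probe sets had log2 ratios of 1.34 and 2.69 for Skil and 1.31 and 2.92 for Smad7, with means of 2.01 and 2.11. Itgae, Ldlrad4 and Pmepa1 belong to this list too. The receptor gene Tgfbr2 was 2.59-fold higher on its brightest probe set, but its 2 measured probe sets pointed in opposite directions (log2 ratios of -0.62 and 1.38), and their mean was 0.38. Of 23 measured genes, 11 were at least 2-fold higher and 3 at least 2-fold lower, the latter Cdkn1a, Cdkn2b and Smad3. Their log2 ratios were -1.43, -1.96 and -1.41, that of Cdkn2b a bound, and a second Smad3 probe set gave -0.13. The list had a median of 0.99 (percentile 100), and of 0.54 (percentile 100) with the mean of all probe sets of a gene.

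Genes typical of tissue-resident and intraepithelial lymphocytes had a median log2 ratio of 1.25 (percentile 100; 0.82 with a pseudocount in place of the floor), and 12 of 22 measured genes were at least 2-fold higher in CD103+ Th1. Itgae, Cdh1, Ldlrad4 and Ahr led this list, which shares 15 of its 29 genes with other lists. The partner chain gene Itgb7 was 2.36-fold higher (6131 against 2602). Prdm1 and Crtam, with log2 ratios of -1.21 and -1.12, were lower, the latter a bound. Other integrin genes did not follow Itgae. Itgb5 was 3.04-fold lower and Itgb3 2.09-fold higher, and the 11 measured integrin genes had a median of 0.14 (percentile 84.5), with 3 at least 2-fold higher and 2 at least 2-fold lower. Chemokine receptor genes moved both ways. Cx3cr1 (at least 4.12-fold) and Ccr8 were higher, and Ccr2 (5.23-fold on its brightest probe set, with log2 ratios from -2.39 to -0.10 over 4) and Cxcr2 (at least 4.47-fold) lower. The 9 measured receptors had a median of 0.50 (percentile 99.7), which fell inside the random range at 0.19 with a pseudocount in place of the floor.

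Interferon-responsive genes were higher in CD103+ Th1, whose medium contained IFN-γ, although Ifng itself was lower there. The immunity-related GTPase gene Iigp1 was 15.7-fold higher (15071 against 959), Irgm1 6.48-fold and Irgm2 3.72-fold. Irf1, a transcription factor induced by IFN-γ, was 4.41-fold higher. All 21 measured genes of the IFN-γ list had log2 ratios above 0, 9 of them at least 2-fold higher, with a median of 0.88 (percentile 100). The type I interferon list, which shares 0 genes with the IFN-γ list, had a median of 0.85 (percentile 100). It had 11 of 23 measured genes at least 2-fold higher and 0 at least 2-fold lower. Among the higher were Rtp4, Xaf1 (3.95-fold), Cmpk2 (at least 3.62-fold) and Irf7 (3.46-fold). Lists without shared genes need not reflect separate responses, and the source of either shift was not tested.

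Cytotoxic genes split. Gzma, which encodes granzyme A, was 8.78-fold higher in CD103+ Th1 (16731 against 1906), and the death ligand gene Tnfsf10, encoding TRAIL, had a log2 ratio of 2.81, with probe sets from 1.18 to 3.30. Prf1, which encodes perforin, was 6.36-fold lower (146 against 928; log2 ratio -0.98 with the higher floor), and Gzmb, for granzyme B, was 1.65-fold lower, with signals of 14358 and 23720. Klrd1, which encodes the NK receptor chain CD94, was 3.76-fold higher and the receptor gene Cd160 3.18-fold higher. The 24 measured genes had a median of 0.08 (percentile 87.2), with 6 at least 2-fold higher and 4 at least 2-fold lower. Cytokine and chemokine genes were also divided. Il9, Tnfsf10 and Xcl1 were higher and Ifng and Csf1 lower. The Csf1 fold was at least 8.14 on the brightest probe set, but 4 probe sets ranged from -3.03 to -0.03 on the log2 scale. The 27 measured genes had a median of -0.05 (percentile 46.7) with 5 at least 2-fold higher and 6 at least 2-fold lower. Among 15 measured genes of the list of inhibitory receptors and exhaustion genes, 3 were at least 2-fold higher and 2 at least 2-fold lower. Cd160 and Cd274, for the ligand PD-L1 (2.32-fold), were among the higher, and Btla (3.44-fold) and Havcr2, for TIM-3 (at least 2.59-fold), were lower. The median of these 15 genes was 0.26 (percentile 96.8).

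Genes of lymphoid homing and of naive or memory T cells were higher in CD103+ Th1. Klf2, a transcription factor that maintains T cell recirculation, was 6.17-fold higher (5221 against 847) and Bcl6 at least 3.36-fold higher. Klf3 was 13.4-fold higher on its brightest probe set, but its probe sets ranged from -0.02 to 3.74 on the log2 scale. Of 16 measured genes, 9 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 1.03 (percentile 100).

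Cholesterol synthesis genes were lower in CD103+ Th1. All 18 measured genes had log2 ratios below 0, with a median of -0.75 that lay below all the matched random lists (percentile 0.00), and 4 were at least 2-fold lower. Hsd17b7 was 2.35-fold lower, Idi1 2.14-fold, Mvd 2.05-fold and Lss 2.05-fold, and Hsd17b7 had probe sets in both directions, from -1.23 to 0.42. With the mean of all probe sets of a gene, 0 of the 18 were at least 2-fold lower and all 18 stayed below 0. All 17 measured glycolysis genes were below 0 as well, by less than 2-fold on their brightest probe sets, and 14 of them after quantile normalization, with Hk2 1.78-fold, Slc2a3 1.67-fold, Egln3 1.64-fold and Pgam1 1.39-fold lower. Slc2a3 probe sets ranged from -2.59 to -0.74. Their median of -0.24 (percentile 4.88) lay inside the range of random lists, but with the mean of probe sets it was -0.27 (percentile 2.26), outside that range. The main medians also lay inside the range for electron transport chain genes, at -0.23 (percentile 4.27), and for unfolded protein response genes, at -0.20 (percentile 5.32). In the former, Ndufa4 was 1.64-fold lower and Sdhb 1.47-fold lower. In the latter, Asns, which encodes asparagine synthetase, was 4.81-fold lower and Dnajb9 1.66-fold higher. None of the 29 measured cell cycle genes differed by 2-fold on its brightest probe set, though Mcm3 probe sets ranged from -1.12 to -0.51. Rrm1 was 1.48-fold lower, Aurkb 1.45-fold and Mcm3 1.43-fold, and the median was -0.12 (percentile 20.6). Small values below 0 were common in lists inside the random range. They made up 24 of 29 cell cycle genes, 19 of 20 electron transport chain genes and 17 of 18 ribosomal protein genes. The sign count of the glycolysis genes is therefore not particular to that list.

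**Figure D3:**
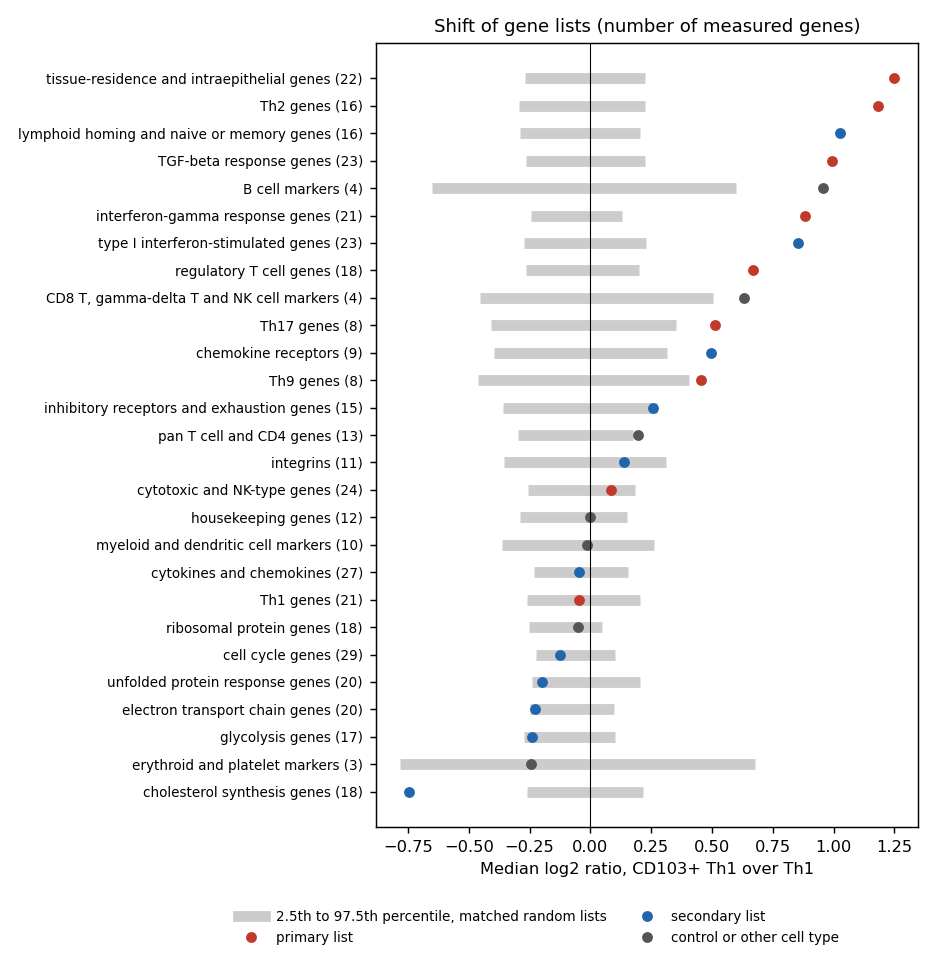
Median log2 ratio (x axis, CD103+ Th1 over Th1) of each gene list (y axis, measured genes in brackets), as red points for primary lists, blue for secondary lists and dark grey for controls and other cell types. Light grey bars span the middle 95% of 10000 random lists of the same size matched on expression. Tissue-residence genes lay highest at 1.25 and cholesterol synthesis genes lowest at -0.75.

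Of 27 lists with at least 3 measured genes, 14 lay outside the 95% range of random lists, 13 higher and 1 lower, where chance would give 1.35. Many lists share genes, among them 12 of the 24 Th2 genes, so the lists are not independent. Random lists are drawn gene by gene, while genes of a list may move together, so 1.35 is a rough guide. Of the 9 primary lists, 7 lay outside the range, and 5 with a floor at the 25th percentile or with a pseudocount. The percentiles describe these 2 arrays and carry no replicate error.

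Pan T cell genes were slightly higher in CD103+ Th1, with a median of 0.20 (percentile 98.0), and Cd4 was 1.11-fold and Cd247 1.55-fold higher. Random lists not matched on expression put that median inside their range (percentile 91.6). Housekeeping genes had a median of 0.00 (percentile 75.6) and ribosomal protein genes -0.05 (percentile 66.6), although Gusb was 2.06-fold and Hprt 1.44-fold lower. Rps19 was 1.25-fold lower and Rps6 1.19-fold.

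Some markers of other cell types were higher in CD103+ Th1. Cd8a, a marker of CD8 T cells, was 4.41-fold higher (2054 against 466) and Cd8b1 2.28-fold higher (1593 against 697). In that list of CD8 T, γδ T and NK cell markers, 4 genes were measured, 5 lay under the floor, and the median was 0.63 (percentile 99.0). It fell inside the random range with a lower floor, at 0.22 (percentile 84.6), and with a pseudocount, at 0.20 (percentile 90.0). With the floor at the 75th percentile it was 1.19 (percentile 99.9) over 3 genes. The T cell receptor γ chain genes Trgv1 (16.5-fold) and Trgv4, with log2 ratios from 0.47 to 1.32 over 3 probe sets, were higher too. Of 12 B cell markers with a named probe set, 8 lay under the floor, including Ms4a1 and Pax5. Ighm was 3.16-fold and Cd79b at least 3.11-fold higher, the median of 4 genes was 0.96 (percentile 99.7), and Ighm probe sets ranged from -0.53 to 1.84. The B cell median turned to -0.28 with a lower floor and to -0.20 with a pseudocount. Among 10 myeloid and dendritic cell markers, H2-Aa (at least 10.2-fold), Mpeg1 (at least 8.41-fold) and Cd74 (2.54-fold) were higher and Cd68 (2.25-fold) and H2-Ab1 (2.14-fold) lower, with a median of -0.01 (percentile 61.6). The 3 measured H2-Aa probe sets ranged from 2.07 to 3.35 on the log2 scale, and with the higher floor H2-Aa and Mpeg1 had log2 ratios of 0.76 and 0.48. Granulocyte markers had 12 genes under the floor and 1, Ngp, measured at 80.3 in Th1 alone. Of erythroid and platelet markers, Car2 was higher and Itga2b 1.48-fold lower, with a median of -0.24 over 3 genes (percentile 23.9).

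Probe sets of one gene served as a check within this pair of arrays. Among 5238 genes with at least 2 measured probe sets, 64.1% had all of them in one direction. Of the 501 such genes with a difference of at least 2-fold, 465 (92.8%) did. The SD of log2 ratios between probe sets of a gene was 0.36, and it was 0.24 for probe sets at 4 times the floor or more on both arrays. Of 83 named genes with a difference of at least 2-fold, 63 kept it under every alternative that measured them. Besides those given above, the higher floor ended it for Cpm, Etv5, Irf7, Itgb5, Itgb3 and Csf1, with log2 ratios of -0.65, -0.61, 0.98, -0.82, 0.73 and -0.44. The mean of probe sets ended it for Il4ra, Ighm and Gusb, at 0.90, 0.74 and -0.94. Dim named genes such as Ccr8 lay under the higher floor on both arrays and were not put to that alternative. The scatter between probe sets is technical and does not replace replicate cultures.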

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

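The tests weighed here, and the genes Gzmk, Nkg7, Ctsw, Trgv4, Blk, Cd22, Cd40, Cd72, Igha, Cd74, H2-Ab1, H2-Eb1, H2-DMa, H2-DMb2 and H2-Oa, were chosen after the results were seen. Probe sets outside the named genes also differed. Among 3249 measured probe sets with no listed gene, 223 were at least 2-fold higher in CD103+ Th1 and 74 at least 2-fold lower. Among 579 measured probe sets with several genes, 25 were higher and 21 lower.

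Cd8a and Cd8b1, the chains of the CD8 receptor, were 4.41-fold and 2.28-fold higher in CD103+ Th1, and Cd4 was 1.11-fold higher. CD8 T cells among the sorted cells, whose stated purity was above 98%, are a candidate source. The test assumed that they would raise both chains by one factor. That holds only if no other cells and no background add to either signal, which was not checked. The log2 ratios differed by 0.95, above the limit of 0.67 set from the scatter between probe sets. The test also asked for more than 1 measured probe set of each gene, and Cd8b1 had 1, at 1.19. Of the 5 probe sets of Cd8a, the brightest had 2.09, 2.14 and 2.16 and the dimmer ones 0.24 and 1.54. With a single Cd8b1 probe set and that assumption unchecked, the difference does not decide the matter. The 4 effector genes that the test named, Prf1, Ccl5, Nkg7 and Gzmk, were all lower (log2 ratios of -2.67, -1.89, -0.90 and -1.68), but Th1 cells make them too, and Gzma, Klrd1, Cd160, Ctsw, Trgv1 and Trgv4, picked later, were higher (3.13, 1.91, 1.67, 1.43, 4.04 and 1.32), Trgv4 with probe sets from 0.47 to 1.32. The CD8 share and an effect of the medium on CD4 T cells cannot be told apart in total RNA of whole cultures. With 1 array per group the difference also has no replicate check.

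H2-Aa and Cd74 of the class II pathway were at least 10.2-fold (probe sets from 2.07 to 3.35 on the log2 scale) and 2.54-fold higher in CD103+ Th1, and the B cell genes Ighm 3.16-fold and Cd79b at least 3.11-fold higher. Carried-over B cells or other class II-bearing cells could raise these. H2-DMa (4.83-fold, with another probe set at a log2 ratio of 1.40), H2-DMb2 (3.88-fold), H2-Oa (2.02-fold), Cd40 (at least 8.93-fold) and Cd72 (3.18-fold) were higher too. So was Igha (13.3-fold, with 85.2 in Th1 close to the floor, 3 probe sets from 3.73 to 4.68 on the log2 scale). Against such cells, the 3 probe sets of H2-Ab1 had log2 ratios from -1.10 to -0.88, and the highest value over H2-Ab1 and H2-Eb1 was 0.26. The signal of H2-Ab1 in Th1 could hide a small share of such cells, so for H2-Aa and Cd74 this stays open. For Ighm and Cd79b, 2 other markers of the fixed B cell list lay above the floor, Blk and Cd22, with log2 ratios of -0.25 and 0.27, too few to decide, and an effect of the medium was not tested.

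Cholesterol synthesis genes were lower in CD103+ Th1 in 18 of 18 cases, with a median log2 ratio of -0.75. A difference between the arrays that depends on signal level is argued against by the random lists matched on mean expression. The median lay below all of them as deposited and after quantile normalization, where it was -0.77. Quantile normalization moved this median little, so on its own it is a weak check. Less proliferation that lowers both sets of genes alike is argued against by the cell cycle genes, whose median was -0.12. Their SD was 0.20 over 29 genes and their lowest value -0.56. However, 24 of the 29 lay below 0 and 5 above, so a smaller drop in proliferation stays open. With the mean of probe sets the cell cycle median was -0.16 (percentile 7.3), and Mcm3 probe sets reached -1.12. An effect of the media or a difference between single cultures may be the reason, and with 1 array per group neither was tested.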

How the results depend on the processing

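All alternatives were planned before the data were examined. The direction of the primary list medians for Th2, regulatory T cell, TGF-β, IFN-γ and tissue-residence genes, and their place outside the random range, held under each alternative, though the TGF-β median was 0.54 with the mean of probe sets. The counts of higher and lower genes moved with the threshold, to 1391 and 1499 at 1.5-fold and 108 and 86 at 4-fold. They moved with the floor, to 974 and 1206 at the 25th percentile and 267 and 199 at the 75th, and with a pseudocount 846 genes were higher and 968 lower. More or fewer dim genes enter at each floor. The Th9 median was 0.13 with the lower floor, -0.10 with the higher floor and -0.021 with a pseudocount. The Th17 median was 0.18 with the lower floor and -0.11 with a pseudocount. The median of B cell markers was -0.28 with the lower floor and -0.20 with a pseudocount. The number of secondary and control lists outside the random range was 7, and 4 with a pseudocount or with probe sets without suffix letters. For the lists, the cause was not tested. Over all list medians and alternatives, 225 values kept their side of the range, 9 lost it, 1 gained it and 5 changed sign after being outside it. Of 83 named genes with at least 2-fold difference, 0 changed sign and 63 stayed at least 2-fold under every alternative that measured them. Genes under the higher floor on both arrays, such as Ccr8 with signals of 273 and 17.6, were not measured with it and count as stable. The 12 highest and 12 lowest genes were picked with all measured probe sets in one direction, so averaging probe sets could not change their sign. A higher floor lowers the bound of dim genes by construction. Setting medians or trimmed means equal could change little, since both nearly matched as deposited. No leave-one-out and no paired analysis was possible because each group had 1 array. Signal over background limits dim genes, whose folds are bounds.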

Other observations

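The gene families below were grouped by symbol after the data were examined, and the genes named here were chosen after their values were seen. Some families had lower and some higher signals in CD103+ Th1, by less than 2-fold in most genes. The lowest median, -1.02, was that of 6 Armcx genes, 3 of them at least 2-fold lower, and 7 Serpinb genes had -0.63, also with 3 at least 2-fold lower. The 47 measured Mrpl genes, for the large subunit of the mitochondrial ribosome, had a median log2 ratio of -0.35, and the 29 Mrps genes of the small subunit -0.36. Genes for ribosome assembly in the nucleolus were lower too, with medians of -0.61 for 11 Utp genes and -0.69 for 8 Rrp genes, as were 18 nuclear pore genes of the Nup family (-0.47) and 7 Cct genes of the cytosolic chaperonin (-0.57). Timm genes (-0.40), Nop genes (-0.45) and Eif genes (-0.20) were lower as well. Other related families lay inside the random range, among them the Rpl (-0.05) and Rps genes (-0.06) of the cytosolic ribosome, Eef genes (-0.17), Ddx genes (-0.07) and Nol genes (-0.33). On the higher side stood Gbp genes (1.00 over 6 genes), Socs genes (0.77 over 7), Parp genes (0.66 over 11) and 254 Zfp zinc-finger genes (0.23). So did genes with Irf symbols (0.81 over 11), which include Irf2bpl and so are not all interferon regulatory factors. Each of these families kept its direction when the arrays were scaled in the 3 other ways. Medians and trimmed means nearly matched as deposited, so only quantile normalization could change much. Of 255 families with at least 6 measured genes, 47 lay outside the 95% range of matched random lists, where chance would give 12.75. That number is a rough guide, as genes of a family may move together.

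Single genes stood out beside these groups. Ahrr, a target and repressor of the aryl hydrocarbon receptor, was 5.97-fold higher in CD103+ Th1, where Ahr itself was at least 10.2-fold higher. The Th1 signal of Ahrr, 82.5, was close to the floor. Socs3, an inhibitor of cytokine signalling, was 3.79-fold higher, Nrarp, a Notch target, 7.59-fold, the water channel gene Aqp3 10.4-fold and the surface receptor gene Cd96 8.02-fold. Anxa1, for annexin A1, was 7.33-fold lower, Nrn1 5.85-fold and Gadd45g 4.18-fold.

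Whether neighbouring genes change together was a hypothesis with its test written before the count was seen. Among measured genes in chromosome order, 112 neighbouring pairs were both at least 2-fold changed in one direction, against a mean of 54.5 and a 95% range of 41 to 68 in 10000 shuffled orders. Pairs changed in opposite directions numbered 40, against 41 to 69. A shared symbol stem, the letters before the first digit, marked 20 of the 112 pairs, among them Il18r1 with Il18rap. The other 92 alone were above the upper limit of 68. They still hold related genes with unlike symbols, such as the chemokine receptor genes Cx3cr1 and Ccr8. Gene families copied in tandem were therefore not fully set aside. Examples of the 112 pairs were Gpr83 with Izumo1r, Cx3cr1 with Ccr8 and Il18r1 with Il18rap. A run of Eri2, Rexo5, Dcun1d3, Lyrm1 and Tmem159 had log2 ratios from -2.74 to -1.09 on the brightest probe sets. Other probe sets of Eri2 and Tmem159 gave -0.07 and -0.48. The reason for the excess was not tested.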
